A study of Mus musculus with 2 samples.

How the data were processed

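Total RNA of cultured neutrophils was measured on 2 arrays, 1 from wild-type and 1 from miR-223 knockout cells, grouped by the genotype in the labels. Per the labels, RNA was extracted with Trizol and biotinylated cRNA was made with the 3' IVT Express kit of Affymetrix, so signals come mainly from the 3' ends of transcripts. The authors deposited 1 linear intensity per probe set and array. The background correction, summarization and normalization behind these intensities are not given in the sources used here. The columns had near-equal quantiles (90th percentiles of 696 and 704), so they were taken to be on a common level and used as deposited, without centring. If they had been normalized together, a global difference in RNA content between the cultures would not be seen in them.

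Of 45101 probe sets, 64 were array controls and were kept for quality values only. Of the remaining 45037, the platform annotation named 34945 for 1 gene, 932 for several and 9160 for none. Probe sets named for several genes or none entered no gene value. Symbols of 34741 probe sets were updated through Entrez identifiers with the RefSeq genes of assembly GRCm38.p6, which was used only for names, chromosomes and gene order. No coordinates are reported, because the build of the array design is not given in the sources used here.

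Intensities were transformed to log2(intensity + 16). This pseudocount shrinks differences of dim genes. A gene took its probe set with the highest mean log2 value over both arrays. A gene counted as expressed when that mean was at or above the median over all probe sets, 5.64 on the log2 scale or an intensity of 33.9. The difference was knockout minus wild type, and genes at 1 or more in size (2-fold) were counted. With 1 array per genotype no test, p-value or standard error was computed. As a measure of spread within these arrays, the SD between expressed probe sets of a gene was pooled over 5017 genes with at least 2 of them. The probe sets of 51.9% of these genes had the same sign throughout, and of 72.3% (47 of 65) where the gene differed by at least 0.5. The first share is close to what random signs would give for genes with 2 probe sets. The sign of a small difference was thus often not reproduced even within these arrays.

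Gene lists were fixed before the data were examined: reported miR-223 targets, 3 classes of granule and maturation genes, cell cycle, myeloid transcription factors, NADPH oxidase, inflammatory cytokines and NF-kB targets, immediate early genes, G-CSF and SCF signalling, interferon stimulated genes, the microRNA pathway, ribosomal proteins, markers of 10 other cell classes, and sex-linked genes. Some genes stand in several lists, such as Gata2 and Kit in the mast cell and basophil and the progenitor lists. For each of the 24 lists the median difference of the expressed members was set against 10000 random lists of the same size, drawn from expressed genes in 20 bins of mean expression. Its percentile among them describes these arrays and is not a p-value. A list with fewer than 3 expressed members got no percentile.

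The genes named were chosen by a rule fixed with the lists. It took the 15 highest and 15 lowest expressed genes whose expressed probe sets had the same sign, which a gene with 1 such probe set always met. It also took up to 4 members of each list with the largest differences and any member at 1 or more. All measured members of the target and sex-linked lists, and the 10 nearest measured genes on each side of the miR-223 gene, could be named. S100a9, Kit, Ctsc, Pik3ap1, Nrd1, Rab3b, Zfyve9, Osbpl9, Ctse, Klhl5, Wfdc17, Wfdc18, Ccl4, Tubb1 and Cd200r3 were named after their values were seen. Csf1r, Adgre1, Ms4a7 and Btg2 were also named afterwards. These and the unexpressed Nfia, Il6 and Xist do not enter the count of named genes under alternatives. A planned search for miR-223 seed matches in 3' untranslated regions was not run, since transcript sequences were not used here.

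Alternatives were a pseudocount of 1 or 64, median centring, quantile normalization of the arrays, subtraction of a loess curve (span 0.3), no expression filter or one at the 75th percentile, the mean of a gene's probe sets, and leaving out probe sets whose suffix marks sequence shared between transcripts. The mean of a gene's probe sets took in those below the expression cut. It could therefore move a gene with 1 expressed probe set. Thresholds of 1.5-fold and 3-fold, counts of probe sets, genes with agreeing probe sets, and list means were also tried. The order of genes along chromosomes was scanned in windows of 5 expressed neighbours, against 10000 random orders of 10991 genes.

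The procedure was tested on simulated data with 11006 genes. It recovered 100% of 100 genes planted at a difference of 2.0 and 100% of 100 planted at 1.5, and counted 0 unchanged genes. The simulated noise was smaller than the SD of the differences in the data (0.18), and no gene was planted near 1. These outcomes therefore set no bound on false counts between the real arrays. Of 200 unchanged random lists 5% lay outside the central 95%, and 100% of lists shifted by 0.2 were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.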

Results

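Messenger RNA was profiled in neutrophils grown from the bone marrow of wild-type male C57BL/6 mice and of male mice of that strain lacking miR-223, a microRNA abundant in the granulocyte lineage. Blood-forming progenitors had been cultured for 6 days with G-CSF, the cytokine that drives granulocyte production, and SCF, the ligand of the receptor Kit. Cycloheximide, which blocks translation, was present at 100 ug/ml for the last 8 min. Each genotype was measured on 1 Affymetrix 3' array. There were no replicates, so no difference has a replicate check and no test was run. All differences below are knockout minus wild type on the scale log2(intensity + 16), and they compare these 2 arrays. The number of arrays limits the precision of every value. The only spread at hand was that between expressed probe sets of the same gene, an SD of 0.144 within these arrays, which is not a replicate error.

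The deposited intensities ran from 4.56 to 29262 on the wild-type array and from 4.49 to 31305 on the knockout array, with medians of 34.1 and 33.7. The most intense gene on both arrays was S100a9, a calcium-binding protein of neutrophils. Of 18193 genes measured, 11006 counted as expressed.

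The labels could be checked only in part. No probe set was named for the miR-223 gene, so the targeted gene itself was not checked. Of the 20 nearest measured genes around it on the X chromosome, 13 were expressed, with differences from -0.33 to 0.22 and a median of 0.03. Msn, the nearest measured gene on one side, gave an intensity of 4416 on the wild-type array and 4496 on the knockout array. Both cultures were labelled male. The Y-linked genes Eif2s3y (521 against 791), Kdm5d (114 against 128) and Uty (89.9 against 109) were expressed on the wild-type and knockout arrays. Uty had probe sets of opposite sign. The difference of Eif2s3y, 0.59, was 0.32 with the mean of all its probe sets, of which 1 was expressed. Xist, transcribed from the inactive X chromosome of females, was not expressed on either array, at intensities of 24.0 and 25.3. The median of the 3 expressed sex-linked genes was 0.24, at the 96.4th percentile of matched random lists. It was 0.062, at the 76.6th, with the mean of a gene's probe sets, and the list mean was 0.32, at the 98.7th.

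The comparison asked how messenger RNA levels in cultured neutrophils differ without miR-223. Few genes differed strongly. By at least 2-fold, 11 expressed genes were higher in the knockout array and 5 were lower. The highest were Apoe, a lipoprotein component made by macrophages, at an intensity of 156 on the wild-type array and 473 on the knockout array (1.51), and Itgb3, the platelet integrin beta chain (1.34). Ctsl, the lysosomal protease cathepsin L and a reported target of miR-223, had intensities of 1099.6 and 2619 (1.24). The lowest genes without expressed probe sets of opposite sign were Cd300ld, a myeloid receptor (-1.12), and Ppbp, a platelet chemokine (-1.06). Ppbp had intensities of 465 on the wild-type array and 215 on the knockout array. Asprv1, an aspartic protease, stood at -1.02 and Ctla2a, a cathepsin L inhibitor family member, at -1.01.

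The other genes at least 2-fold higher were Nnmt, an enzyme that methylates nicotinamide (1.22), Tax1bp3 (1.19), Nlrp12, a NOD-like receptor of myeloid cells (1.13), Igfbp6, a binding protein of insulin-like growth factors (1.08), Mgam, a glucosidase (1.08), Cbr3, a carbonyl reductase (1.04), Lrrc28 (1.01) and Bmf, a pro-apoptotic BH3-only protein (intensities of 51.3 and 119). Below that size were Foxd4 (0.96), Steap4, a metalloreductase (0.93), Siglecf, a lectin of eosinophils (0.92), and Tmem106b (0.92). On the lower side followed the lipases Lpl (-0.99) and Lipg (-0.95), Cdk5rap1 (-0.99), Btf3l4 (-0.93), Kti12 (-0.92), Prg3, an eosinophil granule protein (-0.92), the platelet chemokine Pf4 (-0.91), Txndc12 (-0.89), Ankrd37 (-0.86), Acod1, the itaconate-producing enzyme of activated myeloid cells (-0.85), and the peptide transporter Slc15a2 (-0.84). Btf3l4, Kti12 and Txndc12 lie next to each other on chromosome 4.

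**Figure D1:**
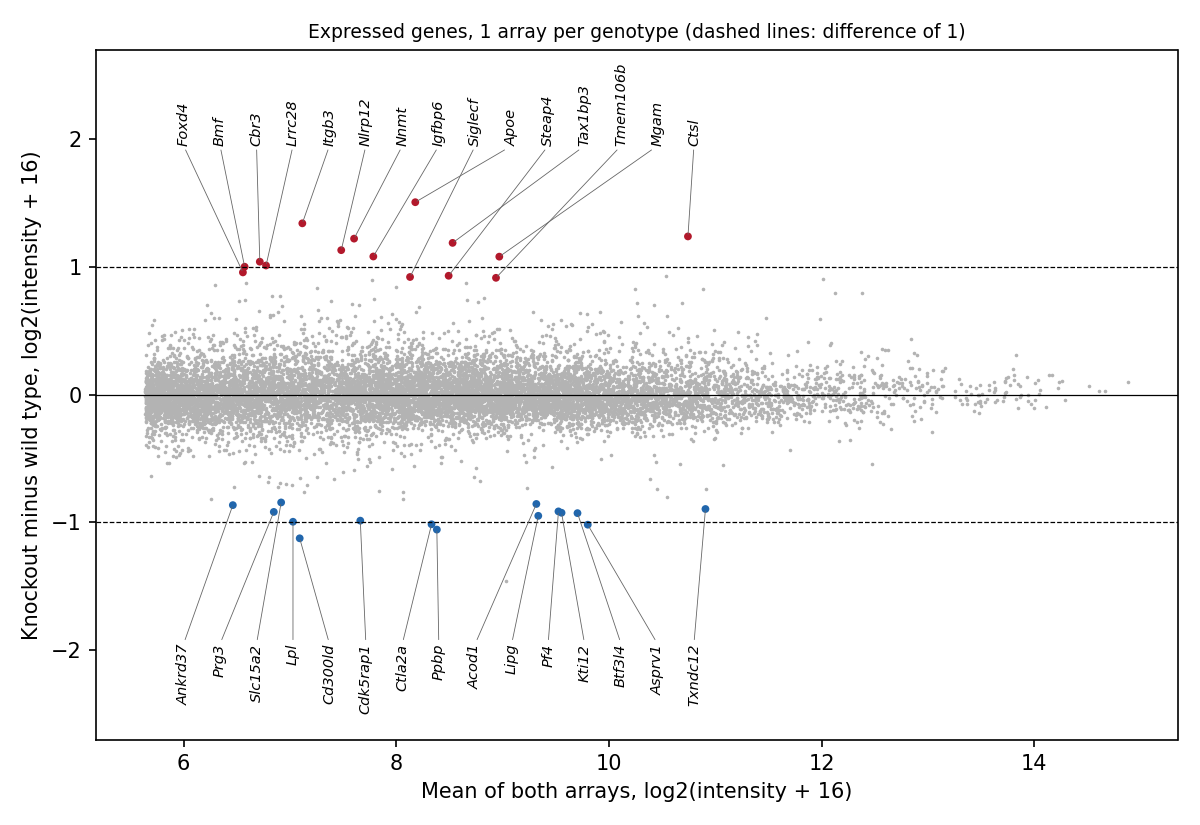
Each point is 1 of 11006 expressed genes, with the mean of both arrays on the horizontal axis and knockout minus wild type on the vertical axis, both as log2(intensity + 16). The 15 highest (red) and 15 lowest (blue) genes whose expressed probe sets had the same sign are named; Apoe is the highest at 1.51, Cd300ld the lowest named gene at -1.12, and most points lie near 0.

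Most of these genes rest on a single probe set. Of the 16 genes at 2-fold or more, 14 had 1 expressed probe set, so no second one could agree or disagree. The fifth lower gene, Pik3ap1, an adaptor of PI3K signalling, stood at -1.46 on its brighter probe set and at 0.06 on the other. The 2 probe sets of Itgb3 gave 0.37 and 1.34. Probe sets of Tmem106b ranged from 0.29 to 0.92 and those of Lipg from -0.95 to -0.070, and with the mean of all probe sets Slc15a2 stood at -0.21. A pseudocount of 64 gave Bmf 0.67, Foxd4 0.63 and Ankrd37 -0.56. Quantile normalization gave 9 higher and 7 lower genes, a pseudocount of 64 gave 3 and 1, and a pseudocount of 1 gave 14 and 10. Across expressed genes the arrays were close, with a Pearson correlation of 0.995 (genes are not independent replicates), an SD of the differences of 0.18, and 79.6% of genes within 0.2. By at least 0.5, 124 genes were higher and 65 lower.

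Genes named in earlier work as targets of miR-223 were higher in the knockout array as a group. Of 17 expressed members, 16 were higher and 1 was lower, with a median of 0.21. This median was above every one of 10000 random lists matched on expression, at the 100th percentile. A high position was not particular to the targets. The G-CSF and SCF signalling list (0.19, 99.9th percentile) and the monocyte and macrophage list (0.17, 99.8th) stood nearly as high. So did the myeloid transcription factors (0.16, 99.8th), which share Mef2c and Lmo2 with the targets. After Ctsl, the largest differences were in Rhob, a small GTPase (0.83), Igf1r, the receptor of insulin-like growth factor (0.63), Sp3, a transcription factor (0.56), and Lmo2, a transcriptional cofactor of blood progenitors (0.39). Cbx5 (0.33), Foxo3 (0.28), Fbxw7 (0.23), Foxo1 (0.21) and Scarb1 (0.17) were next. Mef2c (0.14), Stmn1 (0.14), Ccl3 (0.14), Cxcl2 (0.07), Pknox1 (0.03) and Nlrp3 (0.03) were within the spread between probe sets. The lower expressed member was E2f1, a cell cycle transcription factor (-0.35). Nfia (0.07) and Il6 (-0.34) were measured but not expressed. The list had been written from memory of work on other samples, before the data were examined. Probe sets of Igf1r ranged from -0.07 to 0.63, those of Cbx5 from -0.070 to 0.54 and those of E2f1 from -0.35 to -0.16. With the mean of probe sets Pknox1 stood at 0.25, without shared suffix classes Stmn1 at 0.37, and Nlrp3 turned to -0.0092 under quantile normalization.

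Granule and maturation genes of the neutrophil lineage had small median differences. Several were near the top of the intensity range, with S100a9 the most intense gene on both arrays. Whether such bright signals, here or among the ribosomal protein genes, still rise in proportion to RNA was not tested. The 9 expressed primary granule genes, which are made at the promyelocyte stage, were higher, with a median of 0.15 at the 99.9th percentile. Ctsc had probe sets from -0.15 to 0.24. Examples were Serpinb1a, a protease inhibitor (0.35), Hexa, a lysosomal hexosaminidase (0.22), and neutrophil elastase, Elane (0.16). Of 12 secondary granule genes, 9 were higher and 3 lower, with a median of 0.07 at the 93.0th percentile. Cd177, a neutrophil surface protein, stood at 0.59, whereas Orm1 (-0.39) and the antimicrobial peptide gene Camp (-0.29) were lower. Tertiary granule and mature neutrophil genes were divided, with 8 higher and 8 lower. Their median was 0.0068, at the 58.4th percentile, and changed sign under quantile normalization (-0.0052), while the list mean was 0.075, at the 93.6th. The chemokine Ccl6 (0.72) and the integrin Itgam (0.65) were higher and the peptidoglycan-binding protein Pglyrp1 (-0.54) was lower. The 5 expressed NADPH oxidase subunits, led by Cybb (0.21, or 0.37 with the mean of probe sets) and Cyba (0.13), had a median of 0.07 at the 84.5th percentile.

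Regulators and signalling genes of the lineage were mostly higher. Of 14 expressed myeloid transcription factors, 10 were higher and 4 lower, with a median of 0.16 at the 99.8th percentile; by the mean instead, the percentile was 97.4. Gfi1, a repressor required for granulocytes, stood at 0.41 and Cebpd at 0.29, while Gata2, a factor of progenitors, mast cells and megakaryocytes, stood at -0.53 (-0.20 on its other probe set). Genes of G-CSF and SCF signalling had a median of 0.19 over 11 members, 8 higher and 3 lower, at the 99.9th percentile. They included Socs3, the feedback inhibitor of the G-CSF receptor (0.57, with probe sets from 0.27 to 0.89), Stat3 (0.49, with probe sets down to -0.12) and the receptor Csf3r (0.33). Without probe sets of shared suffix classes this list stood at 0.14, at the upper edge of the central 95% of random lists. Immediate early genes had 14 higher and 4 lower members and a median of 0.12 at the 99.6th percentile. Btg2 counts as higher at 0.050, but its other probe set gave -0.74. Dusp1, a phosphatase (0.47), Zfp36, a destabilizer of messenger RNA (0.35), and Klf2 (0.34) were higher, and Egr1 (-0.53) was lower.

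Proliferation and housekeeping genes were near 0. Of 24 expressed cell cycle genes, 7 were higher and 17 lower, with a median of -0.03 at the 18.5th percentile. Rrm2, a subunit of ribonucleotide reductase, stood at 0.36 (0.56 without shared suffix classes) and Cdk1 at -0.21. The 15 ribosomal protein genes had a median of -0.004 at the 40.9th percentile, which turned to 0.002 under loess, and ranged from Rpl22 (-0.13) to Rps9 (0.080). Without shared suffix classes Rpl22 stood at 0.030 and Rps9 at 0.36. Genes of the microRNA pathway were divided 6 to 6, with a median of -0.002 at the 46.6th percentile. Ago4 (0.44) and Tnrc6b (0.34, with probe sets down to 0.097) were higher. Tarbp2 was lower, at -0.35 on one probe set and -0.014 on the other.

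Inflammatory and interferon genes were more often lower. Of 15 inflammatory cytokine and NF-kB target genes, 6 were higher and 9 lower. Their median was -0.08, at the 2.94th percentile, inside the central 95% of random lists and at percentile 8.92 with the mean of probe sets. It fell outside under loess (2.15), quantile normalization (1.91), no expression filter (0.37) and a stricter one (0.985), and as a list mean of -0.14 (0.08). Tnfaip3, an inhibitor of NF-kB signalling (-0.64, and -0.041 on its other probe set), Cxcl10 (-0.43) and Tnf (-0.39) were among the lower members. Of 6 expressed interferon stimulated genes, 4 were lower, among them Rsad2 (-0.44, or -0.23 with the mean of all probe sets), Oas1a (-0.32) and Irf7 (-0.26). Their median was -0.20, at the 0.19th percentile, and -0.15, at the 2.64th, without probe sets of shared suffix classes. A pseudocount of 64 gave -0.12.

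Markers of several other blood cells that the cultures could hold were lower. The 12 expressed mast cell and basophil markers were lower in the knockout array, with a median of -0.48, below all matched random lists. Kit was within the spread between probe sets (-0.047), and its other probe set gave 0.18. The mast cell proteases Cma1 (-0.76) and Cpa3 (-0.74), the IgE receptor chain Fcer1a (-0.56) and the basophil protease Mcpt8 (-0.55) showed the largest differences. Of 8 megakaryocyte and platelet markers, 7 were lower, among them Ppbp, Pf4 and Vwf (-0.48, or -0.28 with a pseudocount of 64), and Itgb3 was higher. Their median was -0.44, below all matched random lists, and -0.46 without Itgb3. It was -0.26 with a pseudocount of 64 and -0.91 over 3 genes at a stricter filter. Of 4 expressed eosinophil markers, Prg3, Prg2 (-0.73) and Epx (-0.34) were lower and Siglecf was higher. The median of -0.53 was below all matched random lists but rests on few genes, and under a stricter expression filter 2 of them gave 0.10. Without a filter it was -0.22 over 6 genes, and the list mean was -0.27.

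Monocyte and macrophage markers were higher, 9 of 11, with a median of 0.17 at the 99.8th percentile, and 0.29 over 7 genes at a stricter filter. Apoe was followed by Ly86 (0.71) and Gpnmb (0.37, or 0.16 with the mean of all probe sets), while Cx3cr1, a receptor of monocytes, was lower (-0.60). The markers Csf1r (0.10, with probe sets from -0.03 to 0.15), Ms4a7 (0.12) and Adgre1 (-0.016) were within the spread between probe sets. Of 7 dendritic cell and MHC class II genes, 5 were lower, including H2-Aa (-0.48, or -0.30 with the mean of probe sets) and Cd74 (-0.22). Their median was -0.17, at the 0.54th percentile, and -0.013, at the 39.5th, without probe sets of shared suffix classes. Quantile normalization put it at the 2.66th, a pseudocount of 64 gave -0.099 at the 2.56th, and the list mean was at percentile 6.42. Of 4 expressed B cell markers 3 were higher, led by Ighm (0.64, with probe sets from -0.14 to 0.94) and Cd79b (0.43). Their median was 0.40, at the 100th percentile, and 0.024, at the 69.9th, over all 9 measured members. With the mean of probe sets it was 0.19, at the 96.9th.

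Other lineages stood inside the central 95% of random lists. The median was -0.07 for 5 T and NK cell markers (21.5th percentile), in which Cd3d stood at -0.81 (-0.50 with a pseudocount of 64) and Nkg7, a cytotoxic granule protein, at 0.47. It was -0.07 for 4 erythroid markers (15.5th percentile), with Epor at 0.18 and Klf1 at -0.17, but 0.024 (57.7th) with the mean of probe sets. It was 0.03 for 3 stromal markers (63.1st percentile), with Vcam1 at -0.052 (0.17 with the mean of probe sets). For 9 progenitor markers it was 0.10, with Hoxa9 at 0.23 (0.038 on its other probe set) and Myb at 0.17.

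**Figure D2:**
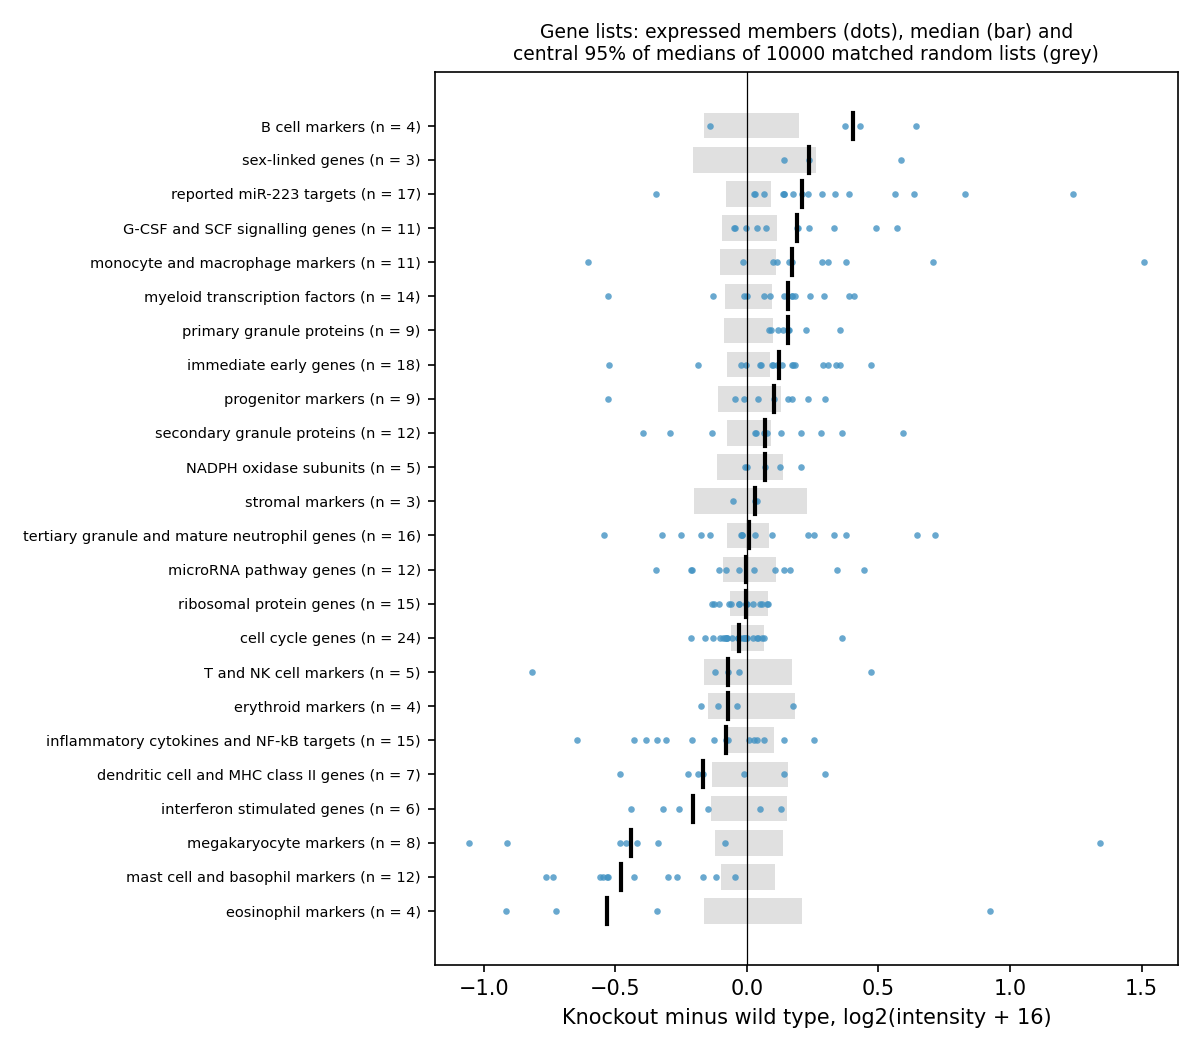
Dots are expressed members of the 24 gene lists, n being their number, and black bars their medians, on a horizontal axis of knockout minus wild type, log2(intensity + 16). Grey shows the central 95% of medians of 10000 random lists matched on expression. The mast cell and basophil (-0.48), megakaryocyte (-0.44) and eosinophil (-0.53) medians lie left of it, and the reported target median (0.21) lies right of it.

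Over the 24 lists, 5 medians were below the central 95% of their random lists and 7 above it, where unrelated genes would put 1.2 outside. Members of a list are co-expressed, so more than that fall outside without any effect of genotype, and the percentiles only describe these arrays. Counts of higher and lower members use 1 probe set per gene, and 32 of the 230 expressed genes in the lists had probe sets of both signs. Many of the 230 had 1 expressed probe set and could not disagree, so the share among the others is larger. In the cell cycle list, 9 of 24 expressed members had probe sets of both signs. The 3' minus 5' log2 signal of beta-actin was 0.33 on the wild-type array and 0.25 on the knockout array, and that of Gapdh 0.15 and 0.06. Spike-in controls were lower on the knockout array. The median difference was -0.11 for the hybridization controls (17 of 18 probe sets lower) and -0.17 for the poly-A controls (24 of 24 lower). No value was adjusted to them, and the poly-A difference is as large as the dendritic cell and MHC class II median (-0.17). The sign of a small difference thus depends on the scale as deposited. Of the 18S ribosomal RNA probe sets, the 5' one had intensities of 493 on the wild-type array and 1149 on the knockout array, the middle one 143 and 153, and the 3' one 176 and 206.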

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

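The alternatives here were planned before the data were examined, except 3 lists without their most divergent member and the scan of neighbouring genes with its windows, chosen after seeing the data. The seed site search and its alternatives were not run. Of 1212 values of 143 named genes under alternatives, 1141 moved by no more than the SD between probe sets and 69 moved further. The other 2 changed the sign of a gene that had differed by at least 2 times that SD, Ctse (-0.17, mean of probe sets) and Klhl5 (-0.24, without shared suffix classes). In all, 13 changed sign. Of 263 values of list medians, 221 stayed within the SD of matched random medians, 39 moved further and 3 changed the sign of a median outside the central 95%. In all, 13 changed sign, the rest for lists inside the central 95%, such as T and NK cells at the stricter filter (0.47, 1 gene). Causes were not tested unless stated.

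Genes higher by 2-fold numbered 3 with a pseudocount of 64, 5 with the filter at the 75th percentile, which tests fewer genes, 7 with the mean of a gene's probe sets, 7 without shared suffix classes, 76 at 1.5-fold and 0 at 3-fold. Genes lower numbered 10 with a pseudocount of 1, 1 with 64, 43 at 1.5-fold, 0 at 3-fold and 11 when probe sets were counted. At a difference of 0.5, the 124 higher genes became 68 with a pseudocount of 64, 67 with the stricter filter, 79 with the mean of probe sets and 279 probe sets; the 65 lower genes became 105 with a pseudocount of 1, 39 with 64, 35 with the stricter filter and 185 probe sets. Probe sets had the same sign in 63.0% of genes at the stricter filter.

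Under median centring, quantile normalization and loess no list median moved beyond its spread. With a pseudocount of 64 the medians moved to -0.12 (interferon), -0.37 (mast cell and basophil), 0.30 (B cell) and -0.26 (megakaryocyte), and with 1 the megakaryocyte median moved to -0.52. Without a filter they were 0.13 (G-CSF and SCF), -0.36 (mast cell and basophil), -0.22 (eosinophil) and 0.024 (B cell). With the stricter filter they were 0.13 (G-CSF and SCF), 0.29 (monocyte), -0.54 (mast cell and basophil), 0.64 (B cell, 1 gene) and -0.91 (megakaryocyte, 3 genes). There the eosinophil median reversed to 0.10 (2 genes) and that of the second mast cell and basophil list to 0.038 (2 genes). The second megakaryocyte list reversed to 0.13, at the 95.6th percentile (6 genes). Its brighter members thus had a median of the other sign than the whole list, and why was not tested. The mean of probe sets gave -0.34 (mast cell and basophil) and 0.19 (B cell). Without shared suffix classes the medians were 0.14 (G-CSF and SCF), 0.23 (monocyte), -0.54 (mast cell and basophil), 0.15 (B cell) and -0.013 (dendritic cell). List means were 0.30 (targets), 0.11 (transcription factors), 0.28 (monocyte), -0.42 (mast cell and basophil), -0.27 (eosinophil), -0.30 (megakaryocyte) and -0.091 (dendritic cell). The scans with windows of 4, 5 and 6 genes each found 0 random orders with as low a window. The target list without Ctsl gave 0.19 and the monocyte list without Apoe 0.17. Signal over background limits dim genes such as Itgb3, Bmf and Cd3d, whose differences moved with the pseudocount.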

Other observations

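Along chromosome 4, 4 neighbouring genes stood lower together in the knockout array, in a run singled out after its values were seen. The knockout over wild-type intensity ratio was 0.519 for Btf3l4, 0.535 for Txndc12, 0.520 for Kti12, a tRNA modification factor, and 0.571 for the protease gene Nrd1. The dim gene Rab3b, between Kti12 and Nrd1, had a ratio of 1.09, and the flanking genes Zfyve9 and Osbpl9 had 0.983 and 1.02. The highest window of 5 neighbours lay on chromosome 11 and held Ccl6 (0.72), Wfdc17 (0.80) and Wfdc18 (0.67), at a median of 0.67. The chemokine genes Ccl3 (0.14) and Ccl4 (0.0068) in that window were within the spread between probe sets. The highest window of 4 lay on chromosome 7, at a median of 0.53. It held Lrrc28 (1.01) and Igf1r (0.63), a reported target of miR-223. Whether Igf1r and its neighbours share a cause was not tested, and high windows were not set against random orders. Elsewhere, probe sets of Ctse, the aspartic protease cathepsin E, gave 0.90 and -1.23, and those of Klhl5 gave 0.93 and -0.24. Among 2467 expressed probe sets with no gene name, 0 were higher and 4 lower by 2-fold.

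The tests in the 3 paragraphs that follow were chosen after the results were seen, except the second marker lists, which were written before their values were. The lists and the loess and quantile settings were planned.

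For the 4 genes on chromosome 4, chance order was argued against. Among 10000 random gene orders, 0 held a window of 6 with a median as low as that of the window with all 4. That median was -0.85, against -0.60 at the lowest of the random orders. The lowest windows of 5 and 4 held 3 of the genes, at medians of -0.89 and -0.91. The lowest of the random orders was -0.85 for each, so the margin there was narrower. A faulty probe set was argued against for Btf3l4 and Nrd1, whose 3 other expressed probe sets were lower by -0.53 to -0.73, but not for Txndc12 and Kti12, which had 0 others. A difference in copy number of this segment between the mice may be a candidate explanation, with a median ratio of 0.535 over the 5 expressed genes from Btf3l4 to Nrd1. Rab3b, at 1.09, goes against 1 ratio over the whole segment, but it was the dimmest of the 5 and no DNA was measured, so copy number cannot be told apart from a regulatory effect or other differences between the 2 cultures. The effect of genotype itself stays open and untested.

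Loess and quantile normalization moved single genes by up to 0.20 but the mast cell, basophil and megakaryocyte markers by at most 0.036. Their list medians stayed at -0.44 or lower, so the trend with intensity that these settings remove was too small to give them. The lists had been singled out against random lists matched on mean expression, so this is not separate evidence against intensity-dependent scaling. Smaller shares of these cells in the knockout culture may be the cause, and were tested with second lists. That for mast cells and basophils had a median of -0.15 at the 2.38th percentile, with 4 of 6 genes lower (Cd200r3 -0.49, or -0.27 with a pseudocount of 64), and that for megakaryocytes -0.12 at the 0.535th, with 7 of 13 lower (Tubb1 -0.53, or -0.35 with a pseudocount of 64). Both met the bound of 2.5 written beforehand, but the percentiles ran from 2.03 to 49.5 and from 0.24 to 95.6 over the settings, so after they were seen the bound was required under every setting and both explanations were left open. A lower level of these genes within the same number of cells, by genotype or by culture, cannot be told apart from fewer cells.

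The median of the reported targets was 0.21 after loess and 0.20 after quantile normalization, and these moved each target by at most 0.036. The trend with intensity that they remove was thus too small to give this median, with the same limit from matched random lists. More monocytes or macrophages in the knockout culture may also raise some of them, as Ctsl is abundant in macrophages. The monocyte and macrophage list stood at the 99.8th percentile (99.7 to 100 over the settings). Of its 11 members 9 were higher, Csf1r and Ms4a7 only within the spread between probe sets. More of these cells cannot be told apart from loss of repression by miR-223, since 1 array per genotype does not separate composition from regulation.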
